A study of Drosophila melanogaster with 32 samples.

How the data were processed

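RNA was measured in whole bodies of virgin Drosophila melanogaster by RNA sequencing of 32 libraries. The flies came from 4 laboratory populations, 2 selected for high and 2 for low consumption of 4% sucrose, sampled at generations 9 and 10 of selection, as females and as males, with 2 biological replicates each. Per the labels' protocols, 37 of 205 inbred lines were intercrossed to make the base population. In each generation 100 flies of each sex were scored over 24 hours and 20 were selected. Each library held at least 30 flies aged 3 to 5 days, frozen within one window of the afternoon. Ribosomal RNA was depleted, libraries were made with the dUTP method, which marks the strand, and they were sequenced as 125-base single reads in 2 pools of 16, each in its own lane.

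The deposited values were raw counts of reads per gene, with no normalization, in 1 table of 16859 genes. The submitters' processing notes name cutadapt 1.6, BWA 0.7.10, STAR 2.4.0e and HTSeq (version not given) with genome build BDGP5, without the role of each tool. The annotation release and the strand setting of the counter are not given in the sources used here, so reads of a gene and of an antisense or overlapping partner cannot be told apart. Multiply mapping reads can also be split between near-identical genes. PGRP-SC1a, LysC, LysE, Mst35Ba, Jon25Biii and snRNA:U2:34ABa have such copies, and their values are uncertain for that reason. The authors' column marking expressed genes was TRUE for 12991 genes. The other 3868 genes held 0.0551% of the counts, and 661 genes had no count in any library. Every row had a gene identifier. Symbols were taken from the deposited table and matched to the names of the Release 6 assembly, in which 16496 identifiers were found and 363 were not. Since the counts used an older build, that assembly served only for names and for which genes lie next to each other, and no coordinates are given.

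Library totals ran from 7780613 to 12987848 counts, with a median of 10000451. The counts per gene of replicate libraries were compared with sampling noise. The chi-square statistic per degree of freedom of replicate pairs was 4.87 to 11.4 in females and 5.49 to 9.52 in males, so the 2 replicates of a cell were not copies of one another in any cell. Libraries of different cells were not compared in this way. The square root of the median dispersion used in the main fit was 0.168 in females and 0.149 in males.

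Genes were tested with edgeR 4.0.16 in R 4.3.3: counts were filtered with filterByExpr, scaled by TMM, and fitted with the robust quasi-likelihood model (glmQLFit, glmQLFTest). P-values were adjusted by Benjamini-Hochberg (BH), with a threshold of 0.05. High and low populations were compared within each sex (8 against 8 libraries) with generation as a covariate, and generations with direction as a covariate. Sex and the interaction of direction with sex were fitted on all 32 libraries. Differences between populations used population as a factor with 4 levels. A gene counted as different in both population pairs when high 1 minus low 1 and high 2 minus low 2 both passed with one sign. Log2 CPM values carry a prior count of 2, and a gene with no count in a group was given a bound from a floor of 3 counts over the group's libraries. Standard errors are those of the fitted coefficients, and SDs are over libraries. The 2 replicates of a cell were separate groups of flies from one population. The populations, 2 per direction, were the units that were selected, so p-values over libraries do not separate selection from drift. For that reason counts were also summed per population.

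The population number marks a shared start, at generation 24 or 25 of the intercross, per the labels, and by the reading used here a shared sequencing lane, so it pairs high 1 with low 1 and high 2 with low 2. The labels describe the pools by replicate of the high and low lines, which was read as the population number and not as the biological replicate number. This reading was not tested. Across genes, the difference between population 1 and population 2 among high females correlated at -0.20 with that among low females (-0.04 in males). A lane effect shared within a population number would push these correlations up, so they gave no sign of one. The fit with this number as a block stands beside a result where it moved a count by over 1.5 times or changed a call.

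Before the data were examined, 31 gene lists were fixed, of pathways or gene families and of tissue markers. The families were feeding neuropeptides, insulin and TOR signalling, gustatory receptors, odorant-binding proteins, odorant receptors, digestive proteases, carbohydrate-digesting enzymes, lysozymes and digestive lipases, lipid metabolism, glycolysis and sugar storage, clock genes, biogenic amines, immune genes, detoxification genes, heat shock genes, cuticular proteins, ribosomal proteins and mitochondrially encoded genes. The tissues were ovary (2 lists), testis, accessory gland, spermatheca, fat body, muscle, neurons, photoreceptors, haemocytes, tubule and hindgut, midgut, and sex determination. The mitochondrial list matched no gene and 13 listed names were not found. Lists with at least 5 tested members were tested with camera (limma 3.58.1, preset correlation 0.01), adjusted by BH over 59 tests in both sexes, and again with an estimated correlation, with fry and with the population block. The cuticular name pattern also took Cp1, Cp110 and Cp190, which are not cuticular proteins. Without them the female median was -0.85 and the number of called lists stayed at 21.

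Named genes followed a rule fixed at the same time. Per sex, these were the 6 largest rises and 6 largest falls among called genes with a mean log2 CPM of at least 1 and 1 sign in all 4 combinations of pair and generation. To these came the 2 members with the smallest p of each list under the same conditions, and 20 feeding, insulin and yolk genes whatever their p. For the interaction the 4 largest in each direction were named, between populations the 3 largest, and for sex 10 marker genes. The generation rule named none.

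The test code was tried on simulated counts with 200 genes changed. At 2-fold it recovered 89% in females and 93% in males for high against low, 88% and 93% for generation, 74% for the interaction and 98% for sex. At 1.5-fold it recovered 67% and 75%, 71% and 57%, 28% and 85%. For the high populations it recovered 84% and 90% at 2-fold, and for the low populations 80% and 91%. False calls were 1.89% to 8.12% of calls. The simulated libraries varied independently, with no differences between populations beyond the changed genes, which were drawn from genes with higher counts. These rates therefore do not cover divergence of populations, which the real counts hold. Alternatives were DESeq2 1.42.0 and its size factors, no filter, the population and biological replicate numbers as blocks, a threshold of 0.01, population as a random block (limma voom) or fixed factor, single generations and population pairs, and leaving out each library. Fits without the generation 9 libraries of low population 2 were added after the data were seen. Other splits of the libraries, at most 100 per comparison, were fitted in the same way.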

Results

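Gene expression was measured in whole virgin flies from 4 populations of Drosophila melanogaster, 2 selected for high and 2 for low food consumption. Females and males were sampled at generations 9 and 10 of selection, with 2 biological replicates in each of the 16 combinations of population, generation and sex. Each library held the pooled RNA of at least 30 flies. Deposited read counts per gene totalled 8920823 to 12987848 per female library (median 10645740) and 7780613 to 10383066 per male library (median 9611729). At this depth 10689 genes could be tested in females and 13336 in males. Log2 fold changes are given with their standard error (SE), high minus low unless stated, and adjusted p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg (BH) adjustment.

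More genes differed between the sexes than in any other comparison. Male-limited dosage compensation RNAs roX1 and roX2 were lower in females (log2 -8.82 ± 0.12 and -9.15 ± 0.15). The yolk protein genes Yp1, Yp2 and Yp3 were higher in females by 9.12 ± 0.15, 9.16 ± 0.15 and 8.26 ± 0.12. Sex peptide (SP) and Acp36DE, made in the male accessory gland, differed by -9.36 ± 0.14 and -9.55 ± 0.18, and the testis genes Mst87F and betaTub85D by -8.88 ± 0.15 and -9.16 ± 0.15. Sxl, the switch gene of sex determination, was 1.49 ± 0.05 higher in females. All 10 had edgeR BH-adjusted p of 4.25e-25 or lower with n = 16 per sex. In all, 12885 of 13651 genes differed between the sexes, 5296 higher in females and 7589 higher in males.

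Within each sex, the 2 generation 9 libraries of low population 2 stood apart from the other 14. On the first principal component, which held 31.9% of the variance in females and 18.2% in males, they lay at 58.2 and 46.1 among females, where no other library exceeded 11.0, and at 36.1 and 38.5 among males. Between generations 9 and 10 of this population, 2 libraries against 2, 3519 genes differed in females and 1047 in males by edgeR. In high population 1, high population 2 and low population 1 the counts were 2, 122 and 230 in females. In males they were 259, 67 and 0. In low population 2 all 24 muscle genes were higher at generation 9 in females, with a median log2 difference of 1.66, and 22 of 24 in males, with a median of 1.30. Of the tested cuticular protein genes 20 of 32 were higher in females and 15 of 41 in males (medians 1.43 and 0.41), and 21 of 24 yolk, vitelline membrane and chorion genes were higher in females (median 1.26). Among carbohydrate-digesting enzymes in males 14 of 24 were lower at generation 9, with a median of -0.72.

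**Figure D1:**
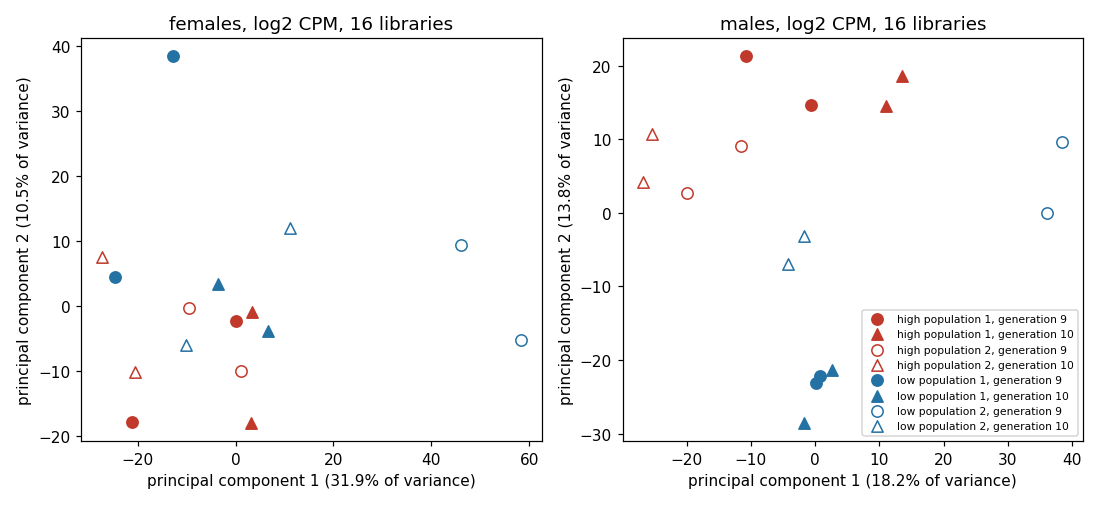
Scores of the 16 libraries of each sex on the first and second principal components of log2 CPM, with the share of variance on each axis; colour marks direction, filled and open symbols populations 1 and 2, circles generation 9 and triangles generation 10. The 2 generation 9 libraries of low population 2 lie at 58.2 and 46.1 on the first axis in females and at 36.1 and 38.5 in males.

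The main question of the series was which transcripts part flies selected for high from flies selected for low consumption. In females, FBgn0010549, which encodes an ABC transporter, rose in the high populations from 2.02 ± 1.11 to 22.5 ± 9.45 CPM (SD, n = 8 libraries per direction), a log2 fold change of 3.48 ± 0.37 (SE; edgeR BH-adjusted p = 1.86e-04). Lsp2 (FBgn0002565), a storage protein of the haemolymph, fell by 3.22 ± 0.49, from 346 ± 212 to 36.0 ± 23.7 CPM (adjusted p = 0.00439). The yolk protein genes Yp3 and Yp2 fell by 0.69 ± 0.09 and 0.57 ± 0.10 (edgeR BH-adjusted p = 7.12e-04 and 0.00712), and Yp1 did not pass at -0.29 ± 0.07 (adjusted p = 0.0562). CG32073 had no count in the 8 high female libraries against 338 in the 8 low ones, which is at least 113-fold lower against a floor of 3 counts over the group. With population as a random block Lsp2, Yp2 and CG32073 did not pass (adjusted p = 0.0711, 0.194 and 0.0606).

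The large changes named here had a mean log2 CPM of at least 1 and 1 sign in all 4 combinations of pair and generation. Outside these limits CG31626 stood at -3.59 ± 0.60 in females. Within them, other large rises in high females were CR43309 (1.88 ± 0.22), the chitinase gene Cht3 (1.74 ± 0.16), the cytochrome P450 gene Cyp6a14 (1.70 ± 0.26), the receptor gene mthl8 (1.50 ± 0.24) and CG12708 (1.47 ± 0.20). The other large falls were CR45600 (-2.54 ± 0.41), CG43085 (-2.32 ± 0.31), the cold-induced gene Fst (-2.28 ± 0.31) and PGRP-SC1a (-1.91 ± 0.31), which encodes a peptidoglycan-degrading amidase. The edgeR BH-adjusted p of these 9 genes ran from 2.74e-05 to 0.0042, with n = 8 per direction, and mthl8 and Fst did not pass with population as a random block (0.109 and 0.0606). In all, 67 genes were higher and 67 lower in high females, 31 of them by over 2-fold, and 131 of the 134 had 1 sign in all 4 combinations of population pair and generation. Counts summed per population, 2 against 2, gave 0 genes by edgeR (340 at unadjusted p under 0.05), the population block gave 215 and a fit with population as a random block 27. The count was 9 and 31 in generations 9 and 10 alone, 462 and 2195 in population pairs 1 and 2 alone, 329 with DESeq2 and 377 with population as a fixed factor. It was 84 without replicate 1 of high population 1 at generation 9 and 86 without replicate 2 of high population 2 at generation 10.

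**Figure D2:**
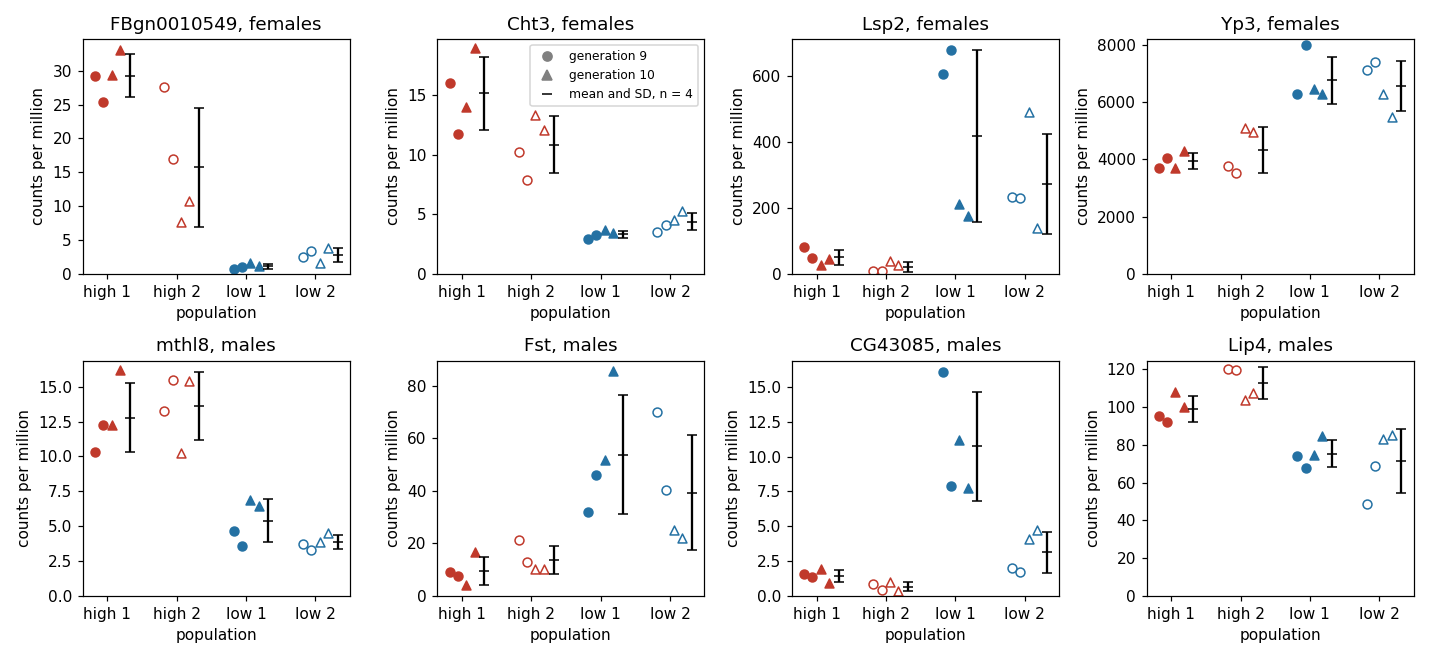
CPM per library of selected genes in high and low libraries of each sex; points are libraries, circles for generation 9 and triangles for generation 10, and bars give the mean and SD of the 4 libraries of a population. Lsp2 averaged 36.0 CPM in high and 346 CPM in low females.

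In females, 16 of the 29 tested gene lists shifted by camera with a preset correlation, and no list passed with an estimated correlation. The yolk, vitelline membrane and chorion list had a median log2 fold change of -0.60 (camera BH-adjusted p = 1.65e-14; adjusted p = 0.526 with an estimated correlation). All 24 members lay below 0. Of these 2 fell over all genes tested, Yp2 and Yp3, and 15 adjusted over the list alone; the median was -0.75 in pair 1 and -0.51 in pair 2. This list moved with the generation 9 libraries of low population 2, and its median was -0.44 without them (adjusted p = 1.59e-08). Germline genes of the ovary lay at 0.08 with 24 of 25 members positive (camera BH-adjusted p = 0.00178; adjusted p = 0.625 with an estimated correlation), 1 of them called, also adjusted over the list alone. It was osk, which directs germ plasm assembly, at 0.18 ± 0.04 (edgeR BH-adjusted p = 0.0251). The germline median was -0.05 in pair 1 and 0.21 in pair 2. Without those 2 libraries it was -0.0014 (camera BH-adjusted p = 0.886).

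Several digestive groups were lower in high females. Carbohydrate-digesting enzymes had a median of -0.22 (camera BH-adjusted p = 1.23e-04; adjusted p = 0.526 with an estimated correlation), with 1 of 24 called, the beta-galactosidase gene Gal (-0.46 ± 0.07), and 6 adjusted over the list alone; the median was -0.22 without the 2 generation 9 libraries of low population 2 (camera BH-adjusted p = 0.00356). Digestive proteases had a median of -0.16 (camera BH-adjusted p = 9.49e-04; adjusted p = 0.625 with an estimated correlation), with 1 of 35 called, Jon25Biii (-0.56 ± 0.11), and 5 adjusted over the list alone. Lysozymes and digestive lipases lay at -0.24 (camera BH-adjusted p = 0.0417, 0.0588 with the population block; adjusted p = 0.570 with an estimated correlation). Of these 17 genes 2 fell, LysC (-1.11 ± 0.19) and LysE (-0.74 ± 0.18), and 3 adjusted over the list alone. Midgut markers had a median of -0.12 (camera BH-adjusted p = 0.00756; adjusted p = 0.607 with an estimated correlation), with 1 of 21 called, PGRP-SC1a, and 6 adjusted over the list alone. The tubule and hindgut list lay at -0.16 (0.02 in pair 1 and -0.33 in pair 2), with 0 of 17 called by edgeR or adjusted over the list alone. Its camera BH-adjusted p was 0.00465, and 0.625 with an estimated correlation. Without the 2 generation 9 libraries of low population 2 the medians of proteases, midgut and tubule were 0.0065, -0.0096 and -0.04, and that of lysozymes and lipases was -0.30, with camera BH-adjusted p from 0.439 to 0.616.

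Fat body markers had a median of -0.52 in high females (camera BH-adjusted p = 1.71e-05; adjusted p = 0.526 with an estimated correlation), with Lsp2 called among 15 and 4 adjusted over the list alone. Haemocyte markers lay at -0.32 (camera BH-adjusted p = 3.56e-04; adjusted p = 0.526 with an estimated correlation), and 1 of 13 was called, also adjusted over the list alone. It was PPO2, a phenoloxidase of crystal cells, at -0.76 ± 0.16. Glycolysis and sugar storage had a median of -0.09 (camera BH-adjusted p = 0.0217; adjusted p = 0.720 with an estimated correlation). Of its 31 genes only the malic enzyme gene Men was called (-0.31 ± 0.06), and adjusted over the list alone 1 was higher and 1 lower. Detoxification genes lay at -0.11, with 1 higher and 4 lower of 85, and 2 and 4 adjusted over the list alone (camera BH-adjusted p = 0.0243; adjusted p = 0.638 with an estimated correlation). Among them Cyp6a14 rose and Cyp6w1 fell by 0.74 ± 0.15. Biogenic amine genes had a median of -0.22 with 0 of 29 called by edgeR or adjusted over the list alone (camera BH-adjusted p = 0.00127; adjusted p = 0.625 with an estimated correlation). Without the generation 9 libraries of low population 2 the medians were -0.27 for fat body, which still passed (camera BH-adjusted p = 0.00639), and -0.12 for haemocytes, -0.0045 for glycolysis, -0.02 for detoxification and -0.02 for amines, which did not (0.0571, 0.910, 0.9999 and 0.616). The detoxification test then pointed upward. Over all libraries 2 of these lists turned in sign between the pairs. The medians in pairs 1 and 2 were 0.04 and -0.23 for glycolysis and 0.05 and -0.36 for amines.

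Structural groups moved with the same 2 libraries. Muscle markers had a median of -0.51 with 0 of 24 called by edgeR or adjusted over the list alone (camera BH-adjusted p = 0.00176; adjusted p = 0.783 with an estimated correlation). Their median was 0.27 in pair 1, -1.22 in pair 2 and 0.15 without the generation 9 libraries of low population 2 (camera BH-adjusted p = 0.581, in the other direction). Cuticular protein genes lay at -0.75 with 0 of 32 called, and 4 lower adjusted over the list alone (camera BH-adjusted p = 1.62e-05; adjusted p = 0.570 with an estimated correlation). Their medians were -0.03 and -0.87 in the pairs and -0.06 without those libraries (camera BH-adjusted p = 0.0765). Genes of 2 male tissues, read at low levels in females, lay higher in high females: testis genes at 0.33 (camera BH-adjusted p = 0.0357; adjusted p = 0.526 with an estimated correlation) and accessory gland genes at 0.76 (camera BH-adjusted p = 7.81e-04; adjusted p = 0.570 with an estimated correlation). None of these 14 and 18 genes was called by edgeR or adjusted over the list alone. Summed over 21 testis genes abundant in males, the level relative to males differed between high and low females by log2 -0.062 (exact permutation p = 0.649), the other direction from the list median. When the generation 9 libraries of low population 2 were left out, the testis list did not pass (median 0.42, camera BH-adjusted p = 0.0571) and the accessory gland list did (0.65, adjusted p = 0.00356).

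The remaining 13 female lists did not pass by camera. Median log2 fold changes were -0.15 for feeding neuropeptides, -0.03 for odorant-binding proteins (1 lower adjusted over the list alone), -0.04 for lipid metabolism and -0.13 for immune genes. Lipid metabolism had 1 called gene, the citrate lyase gene ATPCL (-0.26 ± 0.04), and 3 lower adjusted over the list alone, and the immune list had PGRP-SC1a and 5 lower. The median was 0.0034 for ribosomal proteins, -0.19 for neurons, -0.17 for photoreceptors and 0.02 for sex determination, with 0 called by edgeR or over the list alone in each. Insulin and TOR genes had a median of 0.02 and a mean of -0.03, with Sdr, a secreted binding protein of insulin-like peptides (0.42 ± 0.08), and the amino acid transporter gene mnd (0.21 ± 0.05) called and 3 higher adjusted over the list alone. Medians and means also differed in sign for gustatory genes (-0.06 and 0.12), clock genes (-0.06 and 0.03), spermatheca genes (0.02 and -0.04) and heat shock genes (0.02 and -0.14). Of these only Hsp68 passed, at -0.93 ± 0.17, also adjusted over the list alone. Among genes named from the female lists, edgeR BH-adjusted p ran from 7.12e-04 to 0.049. The calls of mnd, LysE and osk ended without any 1 of 14, 13 and 10 of the 16 libraries (adjusted p up to 0.109, 0.109 and 0.073), and that of Sdr without replicate 2 of high population 2 at generation 10 (0.0502). Both generation 9 libraries of low population 2 left out together ended 2 of the 26 calls, LysE (0.152) and osk (0.0549). With population as a random block 16 of the 26 called genes named in females lost the call. Besides mthl8, Fst, Lsp2, Yp2 and CG32073 these were Sdr, mnd, Jon25Biii, LysC, LysE, ATPCL, Men, Cyp6w1, Hsp68, osk and PPO2, at adjusted p from 0.0589 (ATPCL) to 0.438 (LysE).

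**Figure D3:**
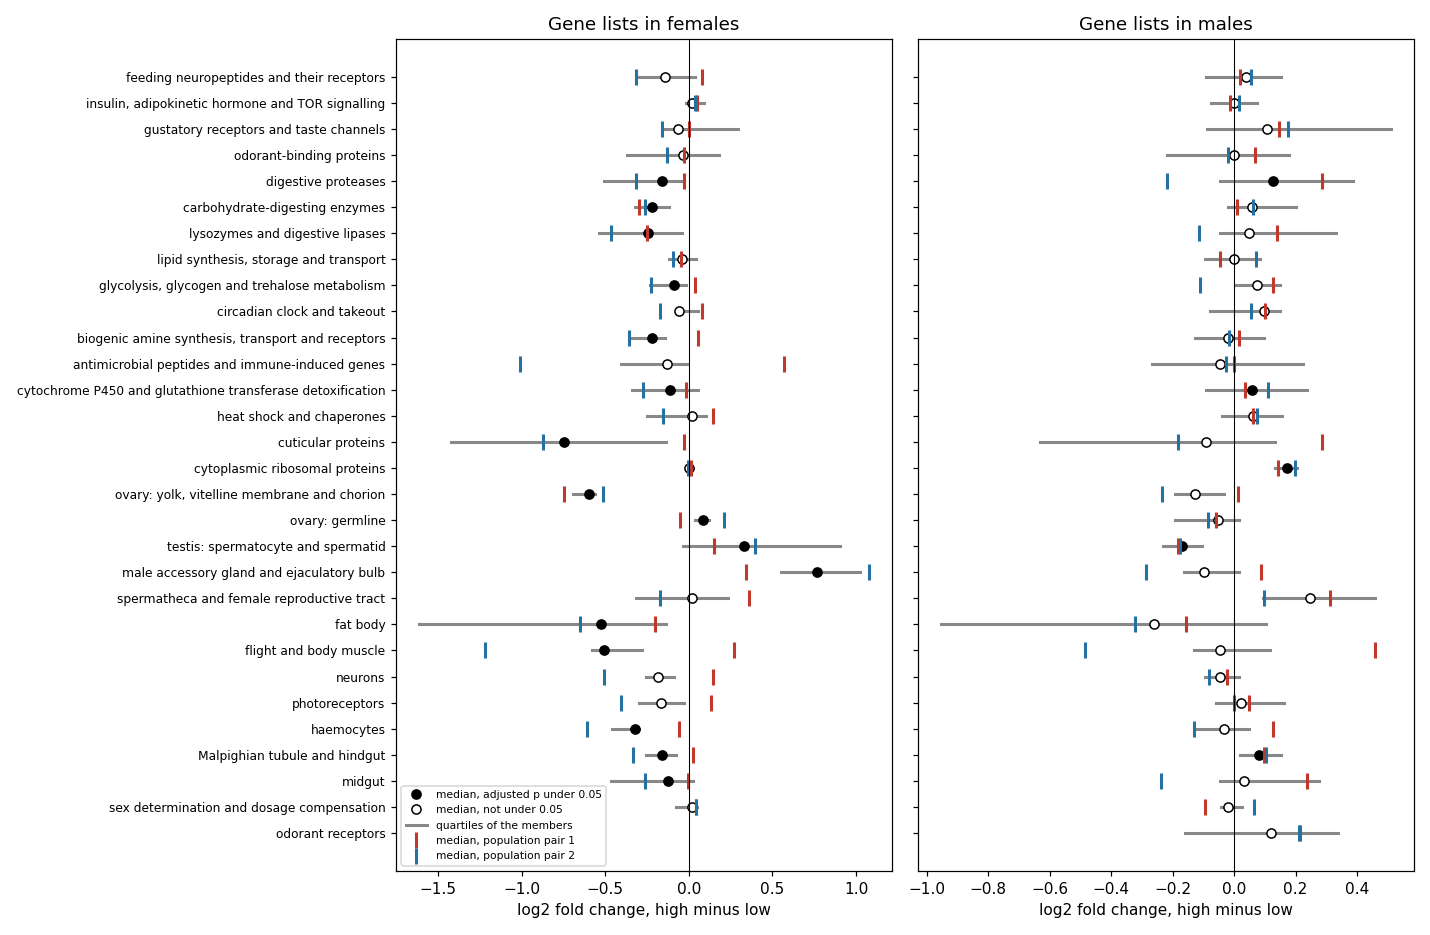
Median log2 fold change, high minus low, of each gene list in females and males, with the quartiles of the members as grey lines and the medians of population pair 1 in red and pair 2 in blue; black points have a camera BH-adjusted p under 0.05 and white points do not. The horizontal axes of the panels differ, and the odorant receptor list has no female value. Yolk, vitelline membrane and chorion genes lie at -0.60 in females and ribosomal proteins at 0.17 in males; with an estimated correlation no list passed in either sex.

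Over all libraries more genes parted the directions in males than in females, and most of them were lower in the high populations. With population as a factor, pair 1 gave 858 genes in males and 215 in females, but pair 2 gave 657 and 978. Among called genes with a mean log2 CPM of at least 1 and 1 sign in all 4 combinations of pair and generation, the largest rises were CG15369 (FBgn0030105; 2.54 ± 0.42), CG33665 (2.08 ± 0.36) and mthl8 (1.53 ± 0.15), and the largest falls CG43085 (-2.73 ± 0.49), CG31626 (-2.63 ± 0.39) and CG43401 (-2.07 ± 0.29). The seminal fluid protein genes Acp54A1 and Acp53Ea fell by 0.79 ± 0.18 and 0.36 ± 0.07, and without the generation 9 libraries of low population 2 Acp54A1 did not pass (adjusted p = 0.0674). Digestive enzyme genes among those that rose were the lipase genes Lip4 (0.54 ± 0.09) and mag (0.41 ± 0.10) and the protease genes Jon65Aii (0.95 ± 0.20) and zetaTry (0.39 ± 0.08).

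Other large changes in males were CR43451 (1.39 ± 0.25), CR44311 (1.37 ± 0.25), CG9825 (1.35 ± 0.40), CR45600 (-2.04 ± 0.44), Fst (-2.03 ± 0.36) and the yellow family gene yellow-e2 (-1.96 ± 0.34). Over these 12 genes edgeR BH-adjusted p ran from 6.06e-06 to 0.0464, with n = 8 per direction, and CG15369, CG9825 and CG43085 did not pass with population as a random block (0.109, 0.133 and 0.0716). In all, 292 genes were higher and 623 lower in high males, 83 of them by over 2-fold, and 884 of the 915 had 1 sign in all 4 combinations of pair and generation. Of the genes lower in high males 87.3% were male-biased, against 45.3% of all genes tested in males; of those higher in high males 43.2% were. Among genes higher in high females 50.7% were female-biased and 11.9% male-biased, and among those lower 11.9% and 35.8%, against 31.2% and 29.8% of all genes tested in females. These shares were not tested. Counts summed per population gave 0 genes by edgeR (1347 at unadjusted p under 0.05), a fit with population as a random block gave 367, and generations 9 and 10 alone gave 112 and 47. The count was 578 without the generation 9 libraries of low population 2, 579 without replicate 1 of low population 1 at generation 10, 595 without replicate 2 of high population 2 at generation 10, and 1379 with population as a fixed factor.

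**Figure D4:**
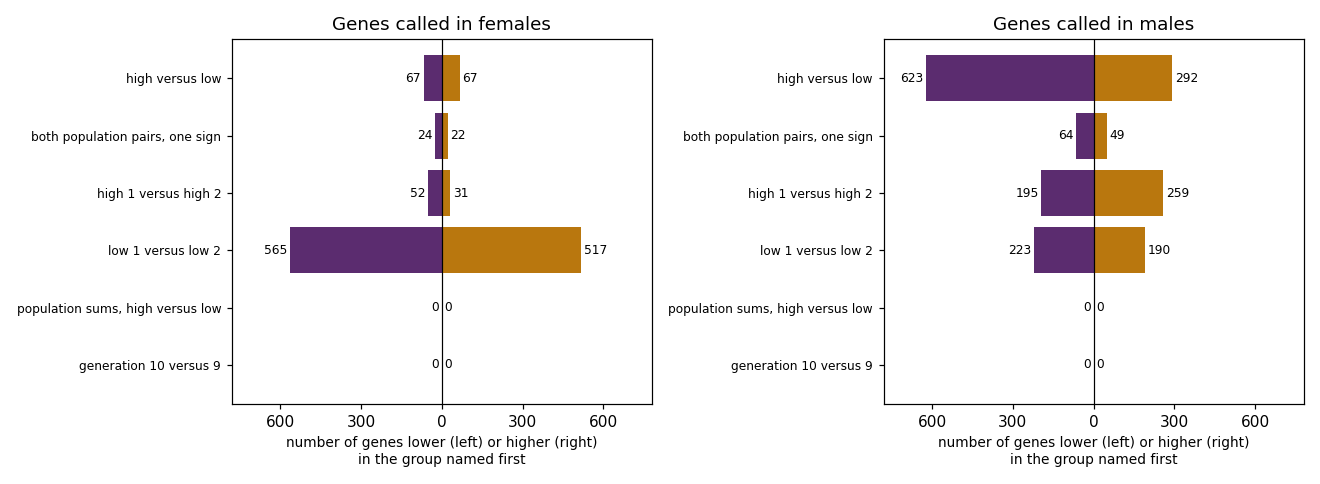
Numbers of genes with edgeR BH-adjusted p under 0.05 in each comparison within females and males, lower (left) or higher (right) in the group named first. In females 67 genes were higher and 67 lower in the high populations, and in males 292 and 623.

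By camera, 5 of the 30 lists tested in males shifted, and none passed with an estimated correlation. Ribosomal proteins had a median of 0.17, 83 of 90 members above 0 and 10 called, with 36 adjusted over the list alone (camera BH-adjusted p = 2.35e-15; adjusted p = 0.570 with an estimated correlation). RpL3 and RpS5a rose by 0.25 ± 0.07 and 0.21 ± 0.06, and the list's median was 0.14 in pair 1 and 0.20 in pair 2. In low population 2 the same list was lower at generation 9 than at generation 10 by a median of -0.19, and without those 2 libraries the median between directions was 0.15 with 1 called. Testis genes had a median of -0.17, with 10 of 33 lower and 13 adjusted over the list alone (camera BH-adjusted p = 1.62e-05; adjusted p = 0.526 with an estimated correlation; fry adjusted p = 0.046). Mst35Ba, a sperm protamine gene, fell by 0.34 ± 0.08 and janB by 0.28 ± 0.07, and without those 2 libraries the median was -0.16 with 2 called. Digestive proteases had a median of 0.13 (0.29 and -0.22 in the pairs), with 3 of 33 higher, and 6 higher and 1 lower adjusted over the list alone (camera BH-adjusted p = 0.0395, 0.0114 without those 2 libraries; adjusted p = 0.625 with an estimated correlation). Detoxification genes lay at 0.06, with 8 of 85 higher and 2 lower, and 10 and 2 adjusted over the list alone (camera BH-adjusted p = 0.0449; adjusted p = 0.625 with an estimated correlation). Those that rose included GstE9 (0.43 ± 0.08) and Cyp4ac1 (0.47 ± 0.09); without those 2 libraries the list's adjusted p was 0.522. The tubule and hindgut list had a median of 0.08, with the proton pump gene Vha68-2 called (0.21 ± 0.05) among 17 and 3 adjusted over the list alone (camera BH-adjusted p = 0.00677, 0.00758 without those 2 libraries; adjusted p = 0.526 with an estimated correlation).

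The other 25 male lists did not pass by camera, though some members did by edgeR. Dh31-R, a diuretic hormone receptor gene, rose by 0.41 ± 0.09 in a feeding neuropeptide list with a median of 0.04. Ilp6, an insulin-like peptide of the fat body, rose by 0.47 ± 0.13 in an insulin list with a median of -0.0004 and a mean of 0.0018. Obp49a rose by 0.51 ± 0.13 among odorant-binding proteins (median -0.0015, test upward), and Or71a fell by 0.56 ± 0.16 among 8 odorant receptors (median 0.12, mean -0.0057). Each of these lists had 1 gene called both over all genes and adjusted over the list alone, save that the odorant receptors had 2 higher and 1 lower adjusted over the list alone. Gustatory genes (median 0.11) had 2 higher, also adjusted over the list alone. The trehalase gene Treh fell by 0.25 ± 0.05 among carbohydrate enzymes (median 0.06), as 1 of 24, also adjusted over the list alone. Lysozymes and lipases (0.05) had 2 higher, 3 adjusted over the list alone. In lipid metabolism (median 0.00067, mean -0.0012) the lipid droplet gene Lsd-1 rose by 0.38 ± 0.08 and the lipophorin gene Rfabg fell by 0.29 ± 0.08, with 2 higher and 2 lower adjusted over the list alone. Fat body markers lay at -0.26, with Lsd-1 and Ugt35b (0.33 ± 0.08) higher and Rfabg lower, and 2 and 4 adjusted over the list alone.

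Among immune genes in males (median -0.05) IM2 and PGRP-SC1a fell by 0.64 ± 0.11 and 0.99 ± 0.27 and Drsl4 rose by 0.61 ± 0.15, with 1 higher and 3 lower called and 1 and 4 adjusted over the list alone. Cuticular proteins lay at -0.09, with Cpr67Fb (-0.74 ± 0.18) and Cpr66D (-0.88 ± 0.23) called, also adjusted over the list alone. Photoreceptor genes (0.02) had 3 higher, also adjusted over the list alone, among them the channel gene trpl (0.33 ± 0.07) and the opsin gene Rh3 (0.29 ± 0.07). Accessory gland genes lay at -0.10, with 2 lower, also adjusted over the list alone. Germline genes of the ovary had a median of -0.05, with orb lower (-0.19 ± 0.05) and 2 adjusted over the list alone. Midgut markers (0.03) had 1 lower, and 1 higher and 1 lower adjusted over the list alone. The spermatheca list, of 7 genes, had a median of 0.25 and a mean of 1.01 with 3 higher adjusted over the list alone. No gene was called by edgeR or over the list alone in glycolysis (0.07), clock (0.10), amine (-0.02), heat shock (0.06), yolk and chorion (-0.13), neuron (-0.05), haemocyte (-0.03), muscle (-0.04, test upward) or sex determination genes (median -0.02, mean 0.01). The male muscle list passed when the generation 9 libraries of low population 2 were left out, with a median of 0.27 (camera BH-adjusted p = 0.00758). That test used the preset correlation only, while the correlation estimated for this list over all libraries was 0.839. Over all libraries its median was 0.46 in pair 1 and -0.48 in pair 2. Genes named from the male lists had edgeR BH-adjusted p from 0.00145 to 0.0372. Of the 41 called genes named in males 10 lost the call without 1 library, at adjusted p up to 0.101 (CG9825, without replicate 2 of high population 2 at generation 10), and CG9825 also with the population block (0.0583). Leaving out both generation 9 libraries of low population 2 ended 12 of the 41: CG9825 (0.126), Obp49a (0.0535), Or71a (0.0713), mag (0.0665), Rfabg (0.0558), Drsl4 (0.0555), Cpr66D (0.0667), RpS5a (0.0771), RpL3 (0.0655), orb (0.0992), Acp54A1 (0.0674) and PGRP-SC1a (0.111). With population as a random block 16 of the 41 lost it. Besides CG15369, CG9825 and CG43085 these were Ilp6, Obp49a, Or71a, mag, Rfabg, Drsl4, Cpr66D, RpS5a, RpL3, orb, janB, Rh3 and PGRP-SC1a, at adjusted p from 0.0510 (janB) to 0.123 (Cpr66D).

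Genes chosen in advance for their part in feeding mostly did not part the directions. Some were read at low levels in whole females, where a change could be missed. Ilp5 read 0.33 and 0.49 CPM in high and low females and Akh 0.80 and 1.31, against 172 and 153 for foxo. In females, neuropeptide F (NPF) differed by 0.21 ± 0.26, its receptor gene NPFR by -0.56 ± 0.30, sNPF by -0.10 ± 0.16 and sNPF-R by 0.27 ± 0.28. The insulin-like peptide genes Ilp2, Ilp3 and Ilp5 differed by 0.20 ± 0.24, 0.12 ± 0.25 and -0.59 ± 0.64, and adipokinetic hormone (Akh) and AkhR by -0.71 ± 0.25 and -0.49 ± 0.20. For Lk, Dsk, takeout (to) and the lipase gene bmm the values were 0.06 ± 0.23, -0.19 ± 0.25, -0.08 ± 0.17 and -0.07 ± 0.06. The insulin-responsive factor gene foxo, at 0.17 ± 0.04, had an edgeR BH-adjusted p of 0.0566, with 0.00624 to 0.999 over the other fits. It passed with the population block (0.0439), DESeq2 (0.0127), population as a fixed factor (0.0176), in pair 1 alone (0.0080), and without replicate 1 (0.0337), replicate 2 (0.0472) or both generation 9 libraries of low population 2 (0.00624). In males NPF, NPFR, sNPF and sNPF-R differed by 0.12 ± 0.18, -0.36 ± 0.22, -0.07 ± 0.08 and 0.07 ± 0.10, and Ilp2, Ilp3 and Ilp5 by -0.23 ± 0.14, -0.23 ± 0.22 and 0.0015 ± 0.35. Male values were -0.15 ± 0.21 for Akh, 0.16 ± 0.11 for AkhR, 0.41 ± 0.17 for Lk, 0.17 ± 0.17 for Dsk, 0.10 ± 0.23 for to, 0.0084 ± 0.06 for foxo, -0.02 ± 0.14 for bmm and 0.45 ± 0.44 for the sugar receptor gene Gr64f. Yp1, Yp2 and Yp3 in males were at -0.18 ± 0.22, -0.11 ± 0.20 and -0.20 ± 0.14. None passed besides Yp2 and Yp3 in females; the lowest other edgeR BH-adjusted p was 0.0562 in females (Yp1) and 0.151 in males (Lk). Yp1 in females passed with DESeq2 (0.0113), population as a fixed factor (0.0405), in pair 1 alone (0.0315), and without replicate 2 of high population 2 at generation 10 (0.0259), replicate 1 of low population 1 at generation 9 (0.0391) or replicate 2 of low population 2 at generation 10 (0.0287). In single pairs NPFR (pair 2, 0.0209) and AkhR (pair 2, 1.77e-04) passed in females and Lk (pair 1, 0.0382) and to (pair 1, 0.0148) in males. Gr5a and Gr43a, and in females Gr64f, had too few counts to test.

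A set of genes moved in one direction in both sexes. Cyp6a14 and mthl8 rose and Fst, CG43085, CR45600, CG31626, PGRP-SC1a and CG32073 fell in high flies of each sex. In all, 13 genes were higher and 21 lower in both sexes, where independent lists would share 1.67 and 1.64, and 3 genes moved in opposite directions. Across the 10410 genes tested in both sexes, which are not independent replicates, the fold changes of females and males correlated at 0.395 (Pearson) and 0.188 (Spearman). Both sexes came from the same 4 populations, so drift of a population enters both.

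The difference between directions itself differed between the sexes for 65 of 13651 genes, 51 with a higher and 14 with a lower value in females than in males. CG32073, with 0 and 3.89 CPM in high and low females against 4.20 and 9.55 in males, had a difference of log2 -7.11 ± 1.32. The sodium channel family gene ppk22 (-2.65 ± 0.43) read 0.249 against 1.92 CPM in females and 26.8 against 31.4 in males, and CG10899 (-2.35 ± 0.51) and phyl (-1.28 ± 0.30) also had lower values. On the other side CG31296 (3.29 ± 0.78) read 0.797 against 0.0753 CPM in females and 8.20 against 8.30 in males. CG14689 (3.70 ± 0.68) and CG43127 (3.61 ± 0.77) rested on 11 and 9 counts in high females against 0 in low ones, at least 3.64-fold and 2.98-fold higher, and CG31851 (3.28 ± 0.67) on 16 against 1, a ratio of 15.9 with a counting interval from 2.47 to 667. In high and low males CG14689 read 47.6 and 55.8 CPM, CG43127 12.9 and 17.1 and CG31851 6.41 and 7.71. All 8 named genes read lower in females than in males. Whether male RNA carried into female libraries adds to these differences was not tested. These 8 genes had edgeR BH-adjusted p from 8.19e-04 to 0.0423 with n = 8 per direction and sex. The count was 38 without the generation 9 libraries of low population 2, 207 with DESeq2, and 128 without female replicate 1 of low population 1 at generation 9.

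Each population pair shared a start generation and, as the labels were read here, a sequencing lane, and some genes parted high from low in both. The log2 fold change of FBgn0010549 in females was 4.62 in pair 1 and 2.44 in pair 2, that of Lsp2 -3.02 and -3.67, and that of Yp3 -0.77 and -0.60. In males mthl8 stood at 1.25 and 1.84 and CG31626 at -2.52 and -2.73. By edgeR, 46 genes passed in both pairs with one sign in females (22 higher, 24 lower), where independent lists would share 9.54, and 26 passed with opposite signs. In males 113 passed with one sign (49 higher, 64 lower; 21.3 for independent lists) and 43 with opposite signs. The counts with opposite signs, 26 and 43, also lay above 9.54 and 21.3, though no value for independent lists was worked out for them. The lists of the pairs thus overlap beyond a common direction, and the excess with one sign overstates what direction adds. Across all tested genes the fold changes of the pairs correlated at -0.04 in females and 0.04 in males. Without the generation 9 libraries of low population 2 the counts were 26 and 73, and leaving out 1 library gave as few as 28 (replicate 2 of low population 2 at generation 9) or 30 (replicate 2 of high population 2 at generation 10) in females and 67 (replicate 1 of low population 1 at generation 10) or 72 (replicate 2 of high population 2 at generation 9) in males. DESeq2 gave 70 and 175.

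Populations selected in the same direction also differed. Among high males, CG33337 was lower in population 1 than in population 2 (0.573 ± 0.601 against 35.5 ± 20.9 CPM, SD, n = 4; log2 -5.75 ± 0.65), CG5892 higher (5.28 ± 0.64) and Lsp2 higher (1018 ± 169 against 100.2 ± 40.6 CPM; 3.28 ± 0.49). Among high females, yellow-e2 had no count in the 4 libraries of population 1 and 55 in those of population 2, at least 17.7-fold lower. In the same comparison snoRNA:Me18S-C1366 (-3.73 ± 0.54) and CG33337 (-3.51 ± 0.55) were lower in population 1. Among low females snRNA:U2:34ABa (6.53 ± 0.43) and CG17470 (4.37 ± 0.46) were higher in population 1 and Diedel, an immune-induced gene, lower (-3.77 ± 1.01). Diedel read 0.360 ± 0.202 CPM in population 1 and 5.36 ± 7.13 in population 2 (SD, n = 4), where the SD exceeded the mean. Among low males the 3 named were snRNA:U2:34ABa (5.73 ± 0.95), CR45119 (-4.87 ± 1.07) and CG5892 (4.59 ± 0.66). CR45119 read 0.182 ± 0.220 CPM in population 1 and 7.56 ± 8.81 in population 2 (SD, n = 4), again with an SD above the mean. All genes named between populations had edgeR BH-adjusted p from 1.55e-06 to 0.0433. In total 83 genes differed between the high populations in females and 454 in males, and 1082 and 413 between the low populations. Without the generation 9 libraries of low population 2 the low count was 90 in females and 309 in males. Leaving out 1 library gave 213 to 3365 genes between low females, 217 to 558 between high males and 50 to 96 between high females, and each library that moved a count by over 1.5 times is named with the sensitivity values.

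Consecutive generations of selection were compared over the 4 populations. No gene passed between generations 9 and 10 by edgeR in either sex, nor by DESeq2, with 238 genes in females and 407 in males at unadjusted p under 0.05. Within populations the muscle list ran in different directions in females: generation 9 minus generation 10 had a median of -0.56 in high population 1, 0.76 in high population 2, -0.65 in low population 1 and 1.66 in low population 2. The generation effect differed between the 4 populations for 2420 genes in females and 972 in males by edgeR.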

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

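The thinning, age, male carry-over rate and first label-swap tests were fixed before their results were seen; the library-total, tissue-mix, marker-gene, whole-population, accessory-gland, replicate-number and yolk tests were chosen after. Within a direction and sex, 321 sets of 8 values were searched for 1 value far from the rest and 10 were found. Chance marks about 1 in 20 groups, which would be 16.

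The libraries of low population 2 at generation 9 stood apart in both sexes, with higher muscle and cuticle transcripts. Thinning all libraries to the smallest total left 100% of the muscle shift, but cannot move a median ratio of abundant genes and so decides nothing, while depth is argued against by the male libraries, which lay below and above generation 10 in total and both at least 1.234 above it in the muscle list, and by females, where the 2 libraries of other populations with totals as high reached 0.3865 against 1.472 and 1.855; a lower share of one tissue raising all others alike is argued against by list medians in males that spanned 1.38 on the log2 scale. Younger flies stay open. The 4 larval serum and fat body genes were all higher in females (median log2 3.45). The 3 tested in males had a median of -1.235, which met the bound set beforehand against this explanation. But these members went both ways (Lsp1alpha -1.24, Lsp1beta -1.47, Fbp1 4.97), a reason stated only after the values were seen. That reason rests on Fbp1, which lay near the floor in males, at 3.62 CPM at generation 9 and 0.0998 at generation 10. Male Lsp1alpha read 6.07 and 14.1 CPM and Lsp1beta 44.4 and 122. In females Lsp1alpha (7.46 and 0.512 CPM), Fbp1 (12.8 and 0.775) and Fbp2 (3.18 and 0.371) also read low. Female Lsp1beta did not pass (edgeR BH-adjusted p = 0.0978). A label swap also stays open: in the planned test the lowest margin of own over other population was -0.653, with both male libraries nearer to high population 1, and 5 more versions chosen afterwards gave mixed answers (0, 2 or 3 of the 4 libraries nearest to their own population in 3 of them, 0.673 for the correlation of the male libraries with genes that part low population 2 from high population 1 in females, and, by markers, at least 8 of 11 of their own, against at most 4 in libraries of the other populations, but up to 6 of 11 of high population 1). The other 12 libraries of generation 9 lay nearest to their own population in the planned test, so no exchanged partner was seen, and a difference in rearing or collection of this population was not tested.

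The generation effect differed between the 4 populations for 2420 genes in females and 972 in males by edgeR, a test of the difference itself. The yolk, vitelline membrane and chorion list kept a median of -0.4447 between high and low females without the generation 9 libraries of low population 2, so these libraries were not its whole source.

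The differences between directions in females and males could come from divergence of the populations unrelated to the direction of selection, and with 4 populations only 3 pairings of whole populations exist, too few for a share under 0.05. The real pairing gave 134 genes in females and 915 in males, and the higher of the other pairings 54 and 97. With population as a factor the real pairing gave 377 in females, close to the 367 of high 1 and low 2 against high 2 and low 1, with a lower variance over genes (0.0747 against 0.0806), while in males it gave 1379 against 452 (0.0735 against 0.0678). Neighbouring genes called in one direction formed 64 pairs in males. Shuffles within chromosome arms and classes of sex bias, 1000 in all, gave a mean of 44.2 (2 as large). Linked haplotypes that differ between the populations would give such an excess for part of the male genes. The test does not single them out, since reads of overlapping partners cannot be told apart. Some pairs were also testis genes, such as ocn and janB (log2 -0.27 and -0.28), whose list lay lower in high males. In females there was 1 neighbouring pair called in one direction, against a shuffled mean of 0.808 (574 as large). Neighbouring genes thus account for little of the female list, and selection on the trait stays open beside drift.

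Transcripts of male glands and testis were read in female libraries, at a median of 0.0984% of the male level for accessory gland genes and 1% for testis genes. Male RNA or barcodes carried over at one rate would give equal levels, but the median ratio of the first to the second was 0.105, which argues against a single rate as the source of both. The accessory gland share was higher in high than in low females by 0.756 on the log2 scale (two-sided exact permutation test, p = 0.0334, n = 8 per direction), while the testis share differed by -0.062 (exact p = 0.649), none of these p-values being adjusted. The shifts differed by 0.818, short of the bound of 1 set for excluding carry-over as the source of the accessory gland shift, so carry-over and expression in females cannot be told apart for it. Over the 16 female libraries the accessory gland share ran from 0.0768% to 0.292%. It and the testis share were higher in biological replicate 1 than in 2 in 7 of 8 combinations each. The mean log2 differences were 0.647 and 0.228 (exact sign permutation p = 0.0547 and 0.0156). With direction permuted within the replicate number the p was 0.018 for the accessory gland and 0.611 for the testis share. The tests of direction took libraries as exchangeable, though each direction held only 2 populations. Their p-values therefore do not separate direction from divergence of the populations. In replicate 2 of population pair 1 both high libraries had a lower accessory gland share than both low ones. In the other combinations of pair and replicate number both high libraries lay above both low ones.

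The difference between directions differed between the sexes for 65 genes by the interaction test. Named among them were CG32073 (log2 -7.11), ppk22 (-2.65), CG10899 (-2.35), phyl (-1.28), CG14689 (3.70), CG43127 (3.61), CG31296 (3.29) and CG31851 (3.28) (fitted values). Some rested on few female counts over 8 libraries per direction, high against low: CG32073 0 and 338, CG14689 11 and 0, CG43127 9 and 0, CG31851 16 and 1. All these named genes read lower in females than in males, and male carry-over was not tested for them.

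Single libraries lay far from the other 7 of their direction and sex. In high females, the mean log2 CPM of odorant-binding proteins was 2.126 in replicate 1 of high population 1 at generation 9, against 2.486 to 2.696 elsewhere. In low females, CR45600 read 3.576 in replicate 2 of low population 2 at generation 9 (2.081 to 2.781 elsewhere) and the accessory gland list 1.27 in replicate 1 of low population 1 at generation 9 (0.4288 to 0.7274). In high males, Drsl4 read 7.25 in replicate 1 of high population 1 at generation 9 (6.391 to 6.71). In low males, CG9825 read -1.671 in replicate 2 of low population 2 at generation 10 (0.02206 to 1.42) and Lip4 5.616 in replicate 1 of low population 2 at generation 9 (6.082 to 6.422). Replicate 1 of low population 2 at generation 10 had list means of 7.661 for glycolysis (7.827 to 7.944) and 3.756 for ovary germline (3.396 to 3.542), and replicate 2 had 6 for heat shock (6.131 to 6.234) and 6.719 for tubule and hindgut (6.498 to 6.597).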

How the results depend on the processing

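Fits without the generation 9 libraries of low population 2 were chosen after the data were seen; the others were planned, and the cause of each change was not tested except where fewer libraries or a stricter threshold made it. Of 871 combinations of a called named gene with another setting, 600 kept the call and 271 lost it with the same sign. Of 1072 that left out 1 library, 964 kept it and 108 lost it. Of 236 for gene lists 180 kept their side, 53 became weaker, 1 stronger and 2 turned, and of 952 for named genes that were not called 865 stayed, 17 passed and 70 turned in sign. A fit that leaves out 1 library assumes that the lone sample of a cell varies like the others. At these depths 10689 of 16859 genes in females and 13336 in males had counts enough to be tested, and no fit varied the depth of a count of called genes. By the reading of the pools used here, the labels give the biological replicate numbers no shared batch; by the other reading they mark the lane. Of the correlations of replicate differences 18 of 28 between female groups and 17 of 28 between male groups were over 0.1. Not every one was, so the replicate numbers were not taken as pairing. The correlations ran from -0.111 to 0.302 in females (median 0.142) and from 0.0328 to 0.192 in males (median 0.112). By edgeR 29 genes in females and 211 in males differed between replicates 2 and 1, so a batch that goes with the replicate number stays open. As a replicate block the biological replicate numbers gave 122 and 1088 genes and, among named genes, ended only the call of mnd in females (edgeR BH-adjusted p = 0.0517).

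With the population number as a replicate block, high against low gave 215 genes in females (1079 in males, from 915), and the block ended the calls of the lysozyme and lipase list in females (0.0588) and CG9825 in males (0.0583), gave a call to foxo in females (0.0439), and changed no other call of a named list. For high against low in females (134) the count was 47 at a threshold of 0.01, 329 with DESeq2, 377 with population as a fixed factor, 27 as a random block, 0 with counts summed per population (340 at unadjusted p under 0.05 by edgeR), 9 and 31 in generations 9 and 10, and 462 and 2195 in pairs 1 and 2. In males (915) these were 263, 1197, 1379, 367, 0 (1347), 112, 47, 1531 and 876. DESeq2 gave 172 and 731 for the high populations in females and males, 1843 and 554 for the low ones, 70 and 175 for both pairs and 207 for the interaction, which was 24 at 0.01. Without the generation 9 libraries of low population 2 the counts were 169 and 578 for high against low, 90 and 309 for the low populations, 26 and 73 for both pairs and 38 for the interaction. Against 21 called lists, 0 passed with an estimated correlation, 1 with fry and 9 without those libraries, which were 8 of the 21 and male muscle (0.00758); the female detoxification and muscle lists turned in direction there (adjusted p = 0.9999 and 0.5814).

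Leaving out 1 library gave 84 to 198 genes for high against low in females (84 without high 1 generation 9 replicate 1, 86 without high 2 generation 10 replicate 2) and 579 to 998 in males (579 without low 1 generation 10 replicate 1, 595 without high 2 generation 10 replicate 2). For the high populations it gave 50 to 96 in females (52 and 50 without high 1 generation 10 replicates 1 and 2, 52 without either of high 2 generation 10) and 217 to 558 in males (237 and 217 without high 1 generation 10 replicates 1 and 2, 271 and 272 without high 2 generation 9, 217 and 284 without high 2 generation 10). For the low populations it gave 213 to 3365 in females (213 and 276 without low 1 generation 9 replicates 1 and 2, 2048 and 690 without low 1 generation 10, 260 and 230 without low 2 generation 9, 3365 without low 2 generation 10 replicate 1) and 256 to 448 in males (256 without low 1 generation 10 replicate 1). Both pairs gave 28 to 63 in females (28 without low 2 generation 9 replicate 2, 30 without high 2 generation 10 replicate 2) and 67 to 132 in males (67 without low 1 generation 10 replicate 1, 72 without high 2 generation 9 replicate 2), and the interaction 44 to 128 (128 without female low 1 generation 9 replicate 1). Sex gave 13018 to 13102 and generation 0 in each sex. The full count for sex, 12885, lies outside that range. Leaving out 1 library leaves a cell of 1, which loosens the filter, so these counts mix the filter with the influence of the library.

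Among named genes that were not called, signs turned as follows (log2). In females these were, at generation 9 alone, Ilp3 -0.063 and to 0.033; at generation 10 alone, NPF -0.083, Ilp2 -0.27, Lk -0.12 and bmm 0.053; in pair 1, NPFR 0.31, sNPF 0.018, AkhR 0.076, to 0.19 and bmm 0.073; in pair 2, NPF -0.025, sNPF-R -0.15 and Lk -0.18; and without the generation 9 libraries of low population 2, sNPF 0.061 and to 0.11. In males they were Ilp5 -0.012 with the biological replicate block and -0.054 with the random block. At generation 9 alone they were NPF -0.049, sNPF-R -0.040, Yp1 0.31, Yp2 0.35, Yp3 0.12 and bmm 0.44, and at generation 10 alone sNPF 0.038, Ilp5 -0.11, to -0.32 and foxo -0.019. In pair 1 they were NPFR 0.22, sNPF 0.0054, Ilp5 -0.19, foxo -0.18, Gr64f -0.15, Yp2 0.11 and Yp3 0.051, and in pair 2 to -0.29 and bmm 0.099. Without the generation 9 libraries of low population 2 they were Ilp5 -0.058, to -0.030 and foxo -0.034. Leaving out 1 library, ranges that crossed 0 were Lk -0.041 to 0.14 and to -0.18 to 0.028 in females, and Ilp5 -0.11 to 0.14, to -0.054 to 0.23, bmm -0.078 to 0.063, foxo -0.021 to 0.033, Yp1 -0.29 to 0.035 and Yp2 -0.21 to 0.12 in males.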

Other observations

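The splits of the libraries were planned before their results were seen, and the comparison of tissue lists between females and males, like the lists named next, was chosen after the values were seen. In low population 2 at generation 9, lists beyond muscle and cuticle also differed from generation 10. In females 16 of 24 neuronal genes were higher (median log2 difference 0.66), 8 of 15 fat body genes (0.77), 13 of 35 digestive proteases (0.47) and 18 of 31 glycolysis genes (0.30), while 15 of 25 germline genes of the ovary were lower (median -0.28). In males 14 of 46 accessory gland genes were higher and 1 lower (median 0.18), 18 of 85 detoxification genes were lower and 3 higher (-0.21), 14 of 24 carbohydrate-digesting enzymes were lower and 1 higher (-0.72), and 7 of 14 fat body genes were lower and 2 higher (-0.36). Called genes here are those with edgeR BH-adjusted p under 0.05 within that population, 2 libraries against 2.

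Over the 8 combinations of population and generation, the mean of the muscle list in females and in males correlated at Pearson 0.848 (exact permutation p = 0.00496, BH-adjusted 0.00496 over 2 relations) and Spearman 0.69 (exact p = 0.0694). For cuticular proteins the values were Pearson 0.904 (exact permutation p = 0.00451, adjusted 0.00496) and Spearman 0.81 (exact p = 0.0218, adjusted 0.0436). Without low population 2 at generation 9 and high population 2 at generation 10, the cells farthest from the median, Pearson's r was 0.591 and 0.442, so the relations rest on those cells.

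For each count, other splits of the same libraries into groups of the same sizes were fitted, 100 drawn or all 35 where fewer exist. They take libraries as exchangeable and most break up populations, so chance is excluded here only among libraries. For whole populations the 3 pairings are too few for a share under 0.05. High against low keeps populations whole, so likeness among the libraries of a population can raise its count whatever selection did. For high against low females 2 of 100 splits gave as many as the real 134, the other with 1752. The share is under 0.05, but a split with many times the real count points to a structure of the libraries. The share therefore argues only weakly against chance among libraries. Of these splits 36, the real one among them, held equal numbers of population 1 and population 2 libraries on each side. The highest other count there was 0. They balance the population number only and need not part each of the 4 populations evenly. In males 1 of 100 reached 915, with 108 as the highest other. Chance among libraries, in this limited sense, can be excluded for high against low males. The same holds for genes shared by both pairs (46 in females with 0 as the highest other, 113 in males with 1). It holds for the high populations (83 against 0 in females and 454 against 4 in males, 1 of 35 splits each). It also holds for the low populations in males (413 against 3), the interaction (65 against 5) and sex (12885 against 0). Chance cannot be excluded for the low populations in females, where 2 of 35 splits gave as many as 1082 genes. The highest other, 3398, set both generation 9 libraries of low population 2 with replicate 1 of low population 1 and replicate 2 of low population 2 at generation 10. For the generations edgeR called 0 in each sex (238 and 407 at unadjusted p under 0.05, 0 by DESeq2), so all 100 of 100 splits give as many whatever the data and decide nothing; the highest were 2755 in females and 15 in males.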
